A study of Equus caballus with 18 samples.

How the data were processed

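Total RNA from equine synovial fluid was profiled on an Affymetrix equine gene array, in 6 horses at baseline, 24 h and 7 days after 8 mg of isoflupredone acetate in a carpal joint. The deposited values are log2 expression values per probe set, given to 2 decimals, from 1.05 to 13.68, for 30559 probe sets and 18 array columns with no missing value. The submitters' processing notes name RMA, Affymetrix Expression Console and Transcriptome Analysis Console 3.0, with no role or order, and whether all arrays were summarised together is not stated. Array medians ran from 3.64 to 4.04 and the spread of values differed between arrays, so the values had not been given 1 common distribution. For arrays, their number limits the precision. Arrays of saline-injected joints were not used here.

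The table of genes that comes with the probe sets gave 1 symbol for 16789 probe sets, several for 343 and none for 13427. Probe sets with 1 symbol covered 16661 genes, 111 of them with more than 1 probe set, and a gene was represented by its probe set with the highest mean. All probe sets were tested, and only those with 1 symbol were named.

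The day 7 columns of horses 1 and 2 were identical at 99.3% of probe sets. They differed at 212 of 30559 probe sets, none with a gene symbol, by up to 3.87. They were averaged and counted as 1 array, attributed in equal parts to both horses in the block, which leaves 17 arrays with 5 at day 7. The design fixed before the data were examined had 18 arrays, and the fit with both columns kept is among the alternatives, as are fits that give this array to either horse or leave it out.

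Time was compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 9 residual and 4.71 prior degrees of freedom). The labels name the same horses at each time, so the horse was a fixed block; in residuals from the time means, arrays of the same horse had a median correlation of -0.02 over 14 pairs and arrays of different horses 0 over 70 pairs. Benjamini-Hochberg adjustment ran over all 30559 probe sets of a comparison, with a threshold of 0.05 (called). Without the block, limma called 437 probe sets for 24 h against baseline, 9227 for day 7 against baseline, 0 for day 7 against 24 h and 5171 for any difference among the 3 times, against 310, 8343, 0 and 3968 in the paired fit, and camera passed 12, 14 and 16 lists against 13, 14 and 15. The changes in the text are those fitted within horses, so they can differ from the difference of the group means.

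The text names genes by a rule fixed before the data were examined. In each comparison these are the 12 genes with the largest rise and the 12 with the largest fall among those called with the same sign in all horses (6 at 24 h, 5 at day 7, where 1 array stands for horses 1 and 2), or those with the smallest p where fewer than 5 qualified. To these come up to 4 called members of each gene list with the smallest p, or 2 where none was called, and 24 inflammatory, matrix and glucocorticoid-responsive genes whatever their values. The genes that met the first condition numbered 109 higher and 18 lower at 24 h, 2614 and 1229 at day 7, and 0 and 0 for day 7 against 24 h.

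The 32 gene lists of pathways and cell types were tested on 16661 genes with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, then again with an estimated correlation and with fry. The mean change of each list in each horse was tested with a two-sided exact sign-flip test. The shared change at 24 h and day 7 was set beside 100 simulated sets of unchanged groups with a common baseline, from which the overlap of as many top-ranked probe sets per direction as were called was taken too, and beside splits of the horses. Other splits of the arrays, 100 drawn per comparison, show how often a count as large arises. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

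Alternatives fixed in advance were the block (none, or the horse as a random effect), only the arrays compared, quantile normalization, median centring, filters on dim probe sets, a variance trend with robust estimation, array weights, an unadjusted p with a 2-fold change, 1 probe set per gene, and each horse left out. Added later were the treatment of the merged array, each single array left out, and the spread of each array as a covariate. The fit was tested on simulated data with 100 of 30559 probe sets changed 2-fold and 100 changed 4-fold at each time. It called 29% of 2-fold and 80% of 4-fold changes at 24 h with 8 false calls, and 23% and 75% at day 7 with 6 false calls; between day 7 and 24 h, where nothing was changed, it made 0 false calls. A list shifted 2-fold at 24 h was called, and 1 other list passed with it. The simulated noise was drawn independently for each probe set and alike for all arrays. It leaves out the correlation between genes and the differing spread of the arrays, so false calls in the real data may be more frequent.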

Results

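Gene expression was measured with an equine array of 30559 probe sets in total RNA from synovial fluid, the fluid that fills a joint. The 6 horses each received 8 mg of isoflupredone acetate, a synthetic corticosteroid, in a joint of the carpus. Fluid was profiled at baseline, before the injection, then 24 h and 7 days after it. There were 6 arrays at baseline, 6 at 24 h and 5 at day 7. The day 7 columns of horses 1 and 2 held the same value at 99.3% of probe sets, while the next closest pair of columns shared 2.05%, so these 2 columns were counted as 1 sample. All values are log2 expression values, and the number of arrays limits their precision. Arrays of saline-injected joints were not analysed here, so each change is a change with time after the drug, the injection, the repeated sampling and, by day 7, renewed exercise together.

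The first comparison asked which genes differed 24 h after the injection. CD163, a haemoglobin scavenger receptor of macrophages that glucocorticoids are known to induce, rose 27.4-fold, from a mean of 3.64 ± 0.43 (SD, n = 6) to 8.42 ± 1.27 (SD, n = 6). Its log2 change was 4.77 ± 0.37 (SE, n = 6 horses, adjusted p = 0.000132), and it was higher in 6 of 6 horses. MMP1, a collagenase, rose 15.4-fold (log2 change 3.94 ± 0.71, SE, adjusted p = 0.0307), or by 4.79 on the log2 scale (adjusted p = 0.00947) without the 24 h array of horse 2. GPNMB, a membrane glycoprotein of macrophages, rose 15.2-fold (3.92 ± 0.50, adjusted p = 0.00812). FKBP5, a co-chaperone of the glucocorticoid receptor and one of its best known targets, rose 6.89-fold (2.78 ± 0.35, adjusted p = 0.0081). The falls were smaller: GZMB, which encodes the granzyme B of cytotoxic lymphocytes, fell by 1.26 on the log2 scale (SE 0.26, adjusted p = 0.0431), from 6.83 ± 0.34 to 5.57 ± 0.24 (SD, n = 6 each).

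Other genes were among the 12 with the largest rises at 24 h. TREM1, a receptor that amplifies inflammatory signals in myeloid cells, rose by 3.29 ± 0.56 (log2 change, SE). HMOX1, the inducible enzyme of haem breakdown, rose by 3.15 ± 0.45, and CTSB, a lysosomal cysteine protease, by 2.53 ± 0.36. LGALS3, the galectin of activated macrophages, rose by 2.69 ± 0.32. TRIB1, a pseudokinase, rose by 2.69 ± 0.37, and HCAR2, the niacin receptor, by 2.69 ± 0.56. The transcription factor ETS2 rose by 2.99 ± 0.40 and DPYD, an enzyme of pyrimidine breakdown, by 2.72 ± 0.31. Each of these 12 genes was higher in 6 of 6 horses, but MMP1 hardly moved in horse 2, from 4.12 at baseline to 4.20 at 24 h. Among the 12 largest falls were the microRNA genes MIR187 (log2 change -1.40), MIR369 (-1.20), MIR424 (-1.14), MIR124-2 (-1.11), MIR24-2 (-1.04) and MIR219-2 (-1.01). The other falls were those of LOC100050557 (-1.26), the intestinal transcription factor CDX2 (-1.09), the photoreceptor gene RD3 (-1.02), the phosphodiesterase PDE4C (-1.01) and the G protein subunit GNG3 (-0.98). The adjusted p of the falls lay between 0.0236 for LOC100050557 and 0.0499 for MIR424.

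Classical inflammatory and matrix genes chosen in advance were followed at 24 h whatever their values. CXCL8, a neutrophil chemokine, rose by 1.51 ± 0.31 (log2 change, SE, adjusted p = 0.0431), and PER1, a clock gene induced by glucocorticoids, by 1.99 ± 0.37 (adjusted p = 0.0322). DUSP1, a phosphatase that glucocorticoids induce, did not pass the test at a log2 change of 2.09 ± 0.51 (adjusted p = 0.0612), nor did TSC22D3, which encodes the glucocorticoid-induced leucine zipper, at 1.15 ± 0.36 (adjusted p = 0.111), nor ANXA1, which encodes annexin A1, at 1.14 ± 0.37 (adjusted p = 0.123). The others that did not pass were TIMP1 (0.97), TNF (0.66), NR3C1, the glucocorticoid receptor gene (0.43), IL1RN (0.35), IL10 (0.32) and MMP3 (0.25). Log2 changes below 0 that did not pass were those of IL6 (-0.36), COMP (-0.36), ADAMTS4 (-0.33), PTGS2, the inducible cyclooxygenase (-0.30), MMP13 (-0.26), ADAMTS5 (-0.22), ACAN (-0.08) and COL2A1 (-0.07). IL1B, CCL2 and PRG4, the lubricin gene, had no probe set with their symbol.

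For 24 h against baseline, limma called 310 probe sets, 166 higher and 144 lower, which held 120 named genes higher and 21 lower; 6067 probe sets had an unadjusted p under 0.05. The rises lay in bright probe sets and the falls in dim ones: with probe sets in 4 equal classes by mean value, 154 of the higher calls were in the brightest class and 96 of the lower calls in the dimmest. The spread of values within an array, as the SD, was 1.37 ± 0.0931 at baseline and 1.56 ± 0.12 at 24 h (SD, n = 6 arrays each), higher in 5 of 6 horses (exact p = 0.0625, two-sided sign-flip test). The share of higher calls moved from 53.5% to 65.4% after quantile normalization and to 64.6% after median centring. CD163 kept its call in each of 30 settings. FKBP5, GPNMB, LGALS3 and ETS2 lost it in 3 of 30, DDIT4 in 8 of 30, TREM1 in 10 of 30, MMP1 in 13 of 30, PFKFB3 in 14 of 30 and PER1 in 15 of 30. ABCA1 lost it in 16 of 30, IKBKB in 17 of 30, CXCL8 in 20 of 30, VCAN in 21 of 30, HCAR2 in 23 of 30 and KLF6 in 25 of 30. Of the falls, RD3 lost it in 17 of 30, MIR219-2 in 20 of 30, GZMB and CDX2 in 21 of 30, PDE4C in 22 of 30 and MIR187 in 24 of 30. LOC100050557 lost it in 11, MIR124-2 in 16, MIR24-2 in 24 and GNG3, MIR369 and MIR424 in 25 of 29. These 6 of the 12 falls lie in the dimmest class and are absent from the setting that drops it. That class moved down as a whole, with a median change of -0.37, 0 higher and 96 lower calls. Of the 21 rises and 12 falls that the rule names at 24 h, 15 rises and 0 falls kept their call without the 24 h array of horse 2, 2 rises and 0 falls without horse 5, and 1 rise and 0 falls on the arrays of the 2 times alone. The number of falls kept was also 0 without the baseline arrays of horses 2, 3 or 6. The count itself was unsteady: it was 427, 70, 57, 126, 5 and 10 without horses 1 to 6 in turn, and 54 without the 24 h array of horse 2, which stood with the day 7 arrays, with 44 probe sets in common. It was 1257, 47, 54, 62 and 33 without the baseline arrays of horses 1, 2, 3, 5 and 6, and 90, 46 and 17 without the 24 h arrays of horses 4, 5 and 6. It was 153, 95, 141 and 77 without the day 7 arrays of horses 3 to 6. It was 107 after quantile normalization (101 in common), 164 after median centring, 2 on the arrays of these times alone, and 1, CD163, with each array's spread as a covariate.

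**Figure D1:**
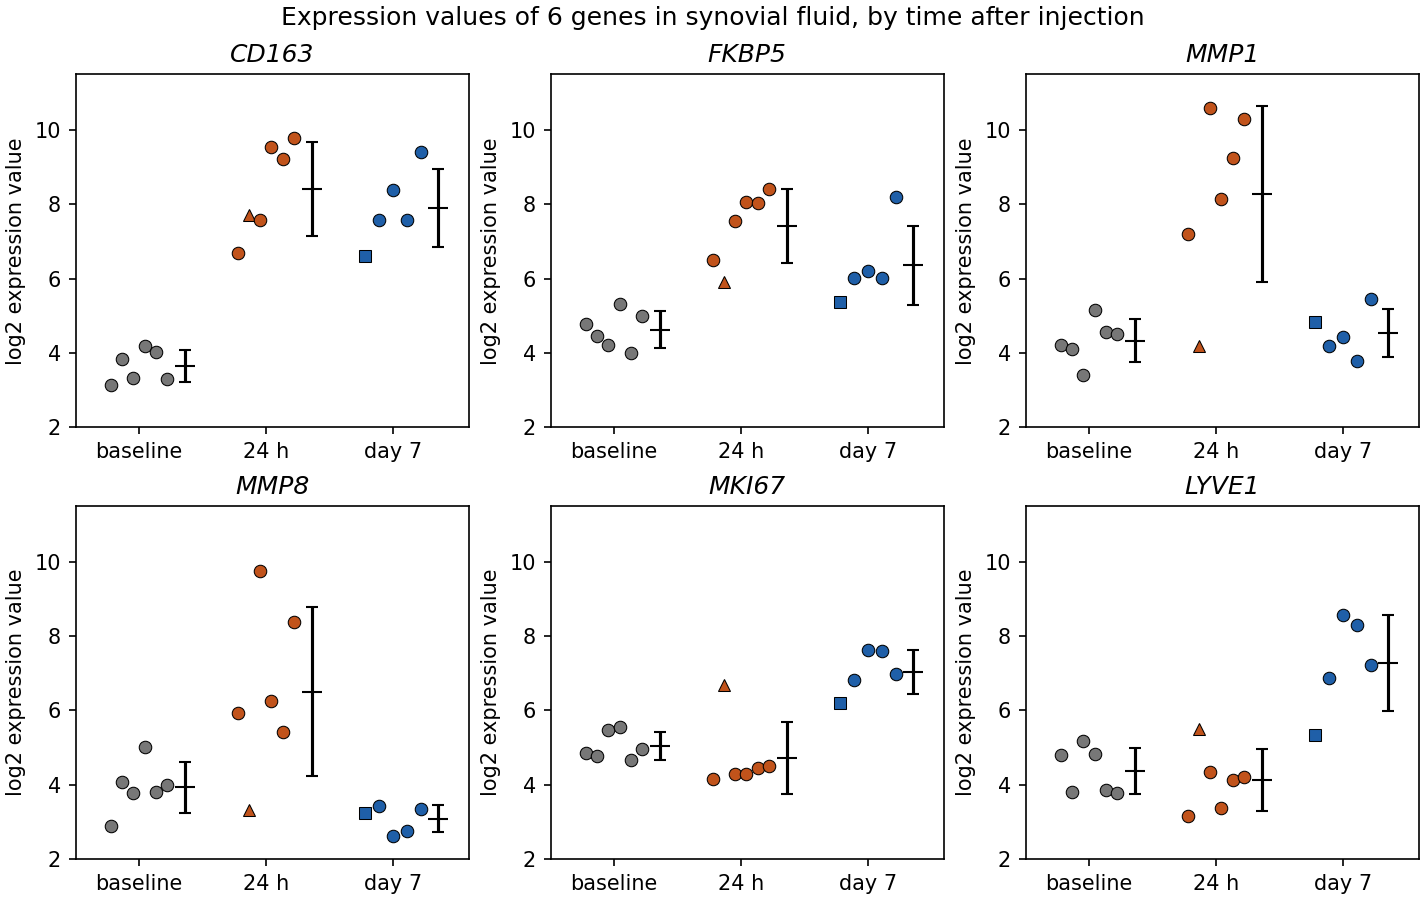
Log2 expression values of 6 genes in synovial fluid at baseline, 24 h and day 7, with 1 point per array and the mean ± SD beside them; the triangle is the 24 h array of horse 2 and the square the merged day 7 array of horses 1 and 2. CD163 was at 3.64 at baseline, 8.42 at 24 h and 7.91 at day 7 on average, while MMP1 was at 4.20 on the 24 h array of horse 2 and between 7.19 and 10.6 on the other 24 h arrays.

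The glucocorticoid-induced genes, a list fixed before the data were examined as were the other lists, passed camera as higher at 24 h. Of its 33 measured members, 5 rose (CD163, FKBP5, DDIT4, MERTK and PER1), 0 fell and the others did not pass; 19 rose and 1 fell when adjusted over the list alone. DDIT4, an inhibitor of mTOR signalling, rose by 2.5 ± 0.39 (log2 change, SE), and MERTK, a receptor with which macrophages take up dying cells, by 2.38 ± 0.36. The median change of the list was 1.07, and camera, which compares a list with all other named genes, gave an adjusted p of 2.41e-13, against an adjusted p = 0.107 with an estimated correlation. The mean change per horse was 1.15 ± 0.54 (SD, n = 6 horses), above 0 in 6 of 6 (exact p = 0.0312, the smallest that 6 horses allow, two-sided sign-flip test). Monocyte or macrophage markers were higher on the same arrays (median 0.74). Without the 24 h array of horse 2 the medians were 0.89 for the glucocorticoid list and 0.38 for the macrophage markers. The glucocorticoid list then had 6 members called, and PER1 was no longer among them (adjusted p = 0.0515).

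In all, 13 of the 32 lists passed camera at 24 h, 12 higher and 1 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.107. Of the monocyte or macrophage markers 1 of 18 rose (CD163), with 6 adjusted over the list alone, a median of 0.74 and an adjusted p of 4.58e-05 (adjusted p = 0.388 with an estimated correlation). Their mean change was 1.91 in horse 2 and -0.17 in horse 1, and without the 24 h array of horse 2 their median was 0.38 (adjusted p = 0.000936, or 0.5 with an estimated correlation). Lipid and cholesterol handling had 1 of 24 called, ABCA1, the cholesterol exporter (1.75 ± 0.33, SE), and 9 higher and 1 lower adjusted over the list alone (median 0.79, adjusted p = 4.58e-05). Hypoxia and glycolysis had 1 of 27 called, PFKFB3, an activator of glycolysis (1.86 ± 0.34), and 9 adjusted over the list alone (median 0.71, adjusted p = 4.69e-05). The adjusted p with an estimated correlation was 0.388 for both lists. NF-kB pathway and its early targets had 1 of 23 called, the kinase IKBKB (1.28 ± 0.24), 2 adjusted over the list alone, an adjusted p of 0.00104 and an adjusted p = 0.107 with an estimated correlation. Resident lining macrophage markers had 1 of 14 called, MERTK (4 adjusted over the list alone), and immediate early genes 1 of 19, KLF6 (0.97 ± 0.19, 4 adjusted over the list alone), both at an adjusted p of 0.026. The list of NK or cytotoxic cell markers was lower, with 1 of 17 called, GZMB (1 adjusted over the list alone), at a median of -0.20 and an adjusted p of 0.0359. With an estimated correlation the adjusted p of these 3 lists was 0.589, 0.388 and 0.669. Without the 24 h array of horse 2, ABCA1 (adjusted p = 0.0694), IKBKB (0.0887), KLF6 (0.107) and GZMB (0.123) lost their call, which left 0 called members in their lists. The NK or cytotoxic list then had a median of -0.39 and passed camera (adjusted p = 0.00448), but not with an estimated correlation (adjusted p = 0.505).

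The other lists past camera at 24 h, all higher, held 0 called members over all probe sets. They were heat shock and protein folding (22 measured, median 0.84, adjusted p = 9.96e-05), ribosomal proteins (35, 0.48, 0.000322), toll-like receptors and inflammasome (22, 0.46, 0.000545), mitochondrial respiratory chain (23, 0.48, 0.00157) and anti-inflammatory mediators (19, 0.32, 0.0176). With an estimated correlation their adjusted p was 0.484, 0.687, 0.447, 0.669 and 0.156. Without the 24 h array of horse 2 the median of heat shock was 0.50 (adjusted p = 0.00121, or 0.551 with an estimated correlation). That of the mitochondrial respiratory chain was 0.27 (adjusted p = 0.0499, or 0.761 with an estimated correlation). Adjusted over the list alone, heat shock had 3 higher and 1 lower, toll-like receptors 3 higher, anti-inflammatory mediators 4 higher and the others 0. The directional fry test passed 3 lists, all higher: glucocorticoid-induced genes, NF-kB and anti-inflammatory mediators (adjusted p = 0.00302 each). None of the 32 mean changes per horse passed the exact sign-flip test after adjustment over the lists. The smallest p that 6 horses allow, 0.0312, became 0.25 there, so this test could hardly pass a list. With each array's spread as a covariate 4 lists passed, 2 higher and 2 lower. The mean change per horse of ribosomal proteins was 0.47 as deposited and 0.15 after quantile normalization. The brightest class of probe sets moved up as a whole at 24 h, with a median change of 0.35. Of the lists, only the glucocorticoid-induced genes were set beside random lists of equal brightness.

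The lists that camera did not pass at 24 h held few called genes. Matrix proteases and inhibitors had 2 of 27, MMP1 and CTSB (4 adjusted over the list alone), and structural matrix genes had 1 of 34, the proteoglycan VCAN (1.94 ± 0.39, SE), whose call was lost without the 24 h array of horse 2 (adjusted p = 0.0887). Neutrophil markers had 1 of 15, TREM1, and inflammatory cytokines and chemokines 1 of 27, CXCL8. No member was called among chondrocyte markers (18 measured), endothelial cell markers (15), synovial fibroblast markers (15), apoptosis (20), B or plasma cell markers (13), mast cell, basophil and eosinophil markers (9), dendritic cell and MHC class II (16), complement (16) and T cell markers (23). The same held for red blood cell markers (8), prostaglandin and leukotriene metabolism (22), interferon-stimulated genes (26), hyaluronan and lubricin (11), platelet markers (9) and the cell cycle (32). Adjusted over the list alone, neutrophil markers, B or plasma cell markers and hyaluronan and lubricin had 2 higher each, structural matrix genes and inflammatory cytokines 1 higher each, and the rest 0. The median was below 0 and the mean per horse above it for inflammatory cytokines and chemokines (-0.10 and 0.01), prostaglandin and leukotriene metabolism (-0.12 and 0.03), hyaluronan and lubricin (-0.12 and 0.04) and T cell markers (-0.02 and 0.03). The direction in camera was lower for these 4 lists, and lower for the cell cycle too, whose median was 0.03 and mean 0.02. The adjusted p of camera over these lists ran from 0.0597 for chondrocyte markers to 0.941 for the cell cycle, and the cell cycle change was 0.799 in horse 2 and between -0.302 and 0.0244 in the other horses. Without the 24 h array of horse 2, matrix proteases and inhibitors (median 0.09, adjusted p = 0.0205) and neutrophil markers (median 0.23, adjusted p = 0.0226) passed as higher, the cell cycle (median -0.20, adjusted p = 0.0226) passed as lower, and resident lining macrophage markers no longer passed (adjusted p = 0.058). Without that array the first 3 of these lists had an adjusted p of 0.374, 0.5 and 0.761 with an estimated correlation, so none of them passed.

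The second comparison asked which genes differed 7 days after the injection. Genes of macrophages were again among the largest rises. CD163 was up 17.3-fold (log2 change 4.11 ± 0.39, SE, n = 5, adjusted p = 0.000345), with a mean of 7.91 ± 1.05 (SD, n = 5). SLC31A1, the copper importer, rose 20.1-fold (4.33 ± 0.53, adjusted p = 0.00195), and ABCA6, a lipid transporter, 18.7-fold (4.22 ± 0.64, adjusted p = 0.00354). HMOX1 rose 16.0-fold (4.00 ± 0.47, adjusted p = 0.00173), and MSR1, a scavenger receptor of macrophages, 10.4-fold (3.37 ± 0.55, adjusted p = 0.00448). GZMB fell by 1.70 on the log2 scale (SE 0.27, adjusted p = 0.00448), and CXCR2, the neutrophil receptor for CXCL8, fell by 1.58 (SE 0.28, adjusted p = 0.00567), each lower in 5 of 5 horses.

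The other genes with the largest rises at day 7 were SLC7A8, an amino acid transporter (3.69 ± 0.57, log2 change and SE), AHR, the aryl hydrocarbon receptor (3.69 ± 0.60), GPNMB (3.62 ± 0.53) and PGD, an enzyme of the pentose phosphate pathway (3.43 ± 0.48). They were followed by C3AR1, the receptor for complement C3a (3.36 ± 0.50), CTSB (3.35 ± 0.38) and TIMD4, a receptor for phosphatidylserine on resident macrophages (3.33 ± 0.61). Among the 12 largest falls were the microRNA genes MIR328 (-3.69 ± 0.54), MIR187 (-1.89), MIR218-2 (-1.87), MIRLET7G (-1.81) and MIR424 (-1.60). The others were CTU1, which modifies transfer RNA (-1.64), LOC100050557 (-1.62), the transcription factor ZEB1 (-1.58), LOC100064176 (-1.55) and CLIC5 (-1.54), a chloride channel protein listed as a marker of lining fibroblasts. The 12 rises kept their calls in all 29 settings other than the spread covariate. So did 9 of the 12 falls, with 28 settings for LOC100050557 and MIR424, which lie in the dimmest class. CLIC5 lost its call without horse 5, LOC100064176 without horse 3, and ZEB1 without horse 3, horse 5 or the day 7 array of horse 5.

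Of the genes chosen in advance, TIMP1, an inhibitor of matrix metalloproteinases, rose by 2.94 ± 0.54 (log2 change, SE, n = 5, adjusted p = 0.00627), and ANXA1, a mediator that glucocorticoids induce, by 1.87 ± 0.39 (adjusted p = 0.00916). FKBP5 rose by 1.60 ± 0.37 (adjusted p = 0.0122), and TNF by 1.29 ± 0.40 (adjusted p = 0.0317), a call that ended in 12 of 30 settings. The log2 change of MMP1 was 0.00 ± 0.75, that of DUSP1 0.14 ± 0.54, that of TSC22D3 -0.12 ± 0.38 and that of PER1 0.50 ± 0.39, and none of them passed. The same was true of CXCL8 (0.54), IL1RN (0.75), NR3C1 (0.87), IL10 (0.30), MMP3 (0.09), MMP13 (-0.60), ADAMTS4 (-0.53), COMP (-0.52), PTGS2 (-0.47), COL2A1 (-0.47), IL6 (-0.38), ACAN (-0.34) and ADAMTS5 (-0.33).

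For day 7 against baseline, limma called 8343 probe sets, 3646 higher and 4697 lower, with 3007 named genes higher and 1405 lower. The median change of all probe sets was -0.24 as deposited, -0.06 after quantile normalization and -0.09 after median centring. Of the lower calls 2634 lay in the dimmest of the 4 brightness classes, where 7 were higher; the brightest class had 2410 higher and 513 lower. The spread of values within an array was 1.70 ± 0.119 (SD, n = 5), an increase of 0.335 ± 0.12 that was seen in 5 of 5 horses (exact p = 0.0625, the smallest that 5 horses allow, two-sided sign-flip test). Quantile normalization left 2858 calls, 2646 of them in common with the deposited values, and the share of higher calls moved from 43.7% to 56.4%, or to 60.2% after median centring. With each array's spread as a covariate 0 probe sets were called. The count was 2362, 3953, 1761 and 4520 without horses 3 to 6 in turn, 2577, 4008 and 2541 without the day 7 arrays of horses 3, 4 and 5, and 4476, 5189 and 4816 without the baseline arrays of horses 2, 5 and 6. It was 8199 without the 24 h array of horse 2.

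At day 7, 14 of the 32 lists passed camera, 9 higher and 5 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.444. Of the monocyte or macrophage markers 11 of 18 rose (12 adjusted over the list alone), with a median of 1.81 and an adjusted p of 4.79e-06. Besides CD163 and MSR1, the mannose receptor MRC1 rose by 3.17 ± 0.61 (log2 change, SE) and CD68, a lysosomal protein, by 2.07 ± 0.36. Of the resident lining macrophage markers 6 of 14 rose (7 adjusted over the list alone, median 0.93, adjusted p = 0.000345), among them TIMD4, MERTK (2.82 ± 0.38) and LYVE1, a hyaluronan receptor (2.83 ± 0.55). Of the toll-like receptors and inflammasome 11 of 22 rose (15 adjusted over the list alone, median 0.79, adjusted p = 0.000147), such as TLR8 (2.36 ± 0.42), TLR4 (1.62 ± 0.39) and the adaptor MYD88 (2.12 ± 0.37). With an estimated correlation these 3 lists had an adjusted p = 0.444 each, and with each array's spread as a covariate 4 lists passed, 0 of them higher.

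Growth and metabolism lists made up most of the other higher lists at day 7. In the cell cycle list 21 of 32 rose and 0 fell (26 adjusted over the list alone, median 1.23, adjusted p = 1.51e-09). MKI67, a marker of dividing cells, rose by 2.00 ± 0.40 (log2 change, SE), UBE2C, a ubiquitin-conjugating enzyme of mitosis, by 2.74 ± 0.47, and CCNA2, the cyclin of S phase, by 2.5 ± 0.50. In hypoxia and glycolysis 17 of 27 rose (19 higher and 2 lower adjusted over the list alone, median 1.46, adjusted p = 7.36e-06), such as the glycolytic enzymes PGK1 (2.16 ± 0.39) and GPI (1.96 ± 0.35). In the mitochondrial respiratory chain 15 of 23 rose (19 adjusted over the list alone, median 1.32, adjusted p = 4.04e-07), such as ATP5F1B of ATP synthase (2.64 ± 0.50) and UQCRC2 of complex III (2.09 ± 0.41). In lipid and cholesterol handling 16 of 24 rose (17 adjusted over the list alone, median 1.32, adjusted p = 1.14e-05), such as the fatty acid carrier FABP5 (2.96 ± 0.59) and the nuclear receptor PPARG (2.07 ± 0.39). Their adjusted p was 0.444 with an estimated correlation. In heat shock and protein folding 15 of 22 rose and 1 fell, also when adjusted over the list alone (median 1.29, adjusted p = 0.000181, adjusted p = 0.465 with an estimated correlation), and the chaperones HSP90AA1 (2.02 ± 0.48) and HSPB1 (2.16 ± 0.52) were among the rises. Ribosomal proteins passed as a list (median 0.65, adjusted p = 0.0056, adjusted p = 0.548 with an estimated correlation) with 0 of 35 called, 0 also when adjusted over the list alone. Their mean change per horse was 0.66 as deposited and 0.16 after quantile normalization. Those of the other higher lists ran from 1.04 to 1.78 and from 0.91 to 1.41. The brightest class of probe sets moved up as a whole, with a median change of 0.51. None of the higher lists at day 7 was set beside random lists of equal brightness.

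By camera, 5 lists passed as lower at day 7. Of all 16661 named genes 1405 were called lower, a larger share than among the structural matrix genes. Of the T cell markers 7 of 23 fell (9 adjusted over the list alone), with a median of -0.43 and an adjusted p of 0.00778, such as the kinase ZAP70 (-1.39 ± 0.25, log2 change and SE) and the adaptor LAT (-0.94 ± 0.29). Of the NK or cytotoxic cell markers 3 of 17 fell (3 adjusted over the list alone, median -0.64, adjusted p = 0.00132), GZMB, PRF1, the perforin gene (-1.03 ± 0.23), and FASLG (-0.88 ± 0.25). Neutrophil markers had 3 lower and 1 higher of 15, also when adjusted over the list alone (median -0.50, adjusted p = 0.0257): CXCR2, OLFM4 (-1.08 ± 0.26) and LCN2 (-0.93 ± 0.22) fell, and TREM1, which other myeloid cells also express, rose by 2.10 ± 0.59. Chondrocyte markers had 2 of 18 lower, COL9A2 (-0.87 ± 0.24) and SOX9 (-0.90 ± 0.28), 1 adjusted over the list alone (median -0.41, adjusted p = 0.00555). Structural matrix genes had 2 of 34 lower, COL5A1 (-0.89 ± 0.23) and COL6A2 (-0.99 ± 0.30), and VCAN higher (1.94 ± 0.41); 1 was lower and 1 higher adjusted over the list alone (median -0.34, adjusted p = 0.0422). The mean change per horse of the structural matrix list was -0.13 ± 0.40 (SD, n = 5 horses) as deposited and 0.02 after median centring. With an estimated correlation these 5 lists had an adjusted p of 0.5, 0.463, 0.491, 0.491 and 0.524. The 2 dimmest of the 4 brightness classes moved down as a whole, with medians of -0.61 and -0.30, against -0.04 for all named genes. The mean changes per horse of the 5 lists were -0.42, -0.67, -0.45, -0.43 and -0.13 as deposited. After quantile normalization they were -0.62, -0.70, -0.39, -0.34 and -0.13. None of the 5 was set beside random lists of equal brightness. The directional fry test passed 13 of the 32 lists at day 7, 11 higher and 2 lower, the lower being NK or cytotoxic cell markers (adjusted p = 0.0268) and endothelial cell markers (adjusted p = 0.0117). It did not pass T cell markers (0.0934), neutrophil markers (0.0637), chondrocyte markers (0.0568) or structural matrix genes (0.154).

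The remaining lists did not pass camera at day 7, at an adjusted p of 0.0528 or more. Their counts stand beside those of all 16661 named genes, of which 3007 were called higher and 1405 lower. The shares called higher among glucocorticoid-induced genes, interferon-stimulated genes, NF-kB and anti-inflammatory mediators were close to that overall share. Glucocorticoid-induced genes had 7 of 33 higher and 2 lower, also when adjusted over the list alone (median 0.37, adjusted p = 0.0781), with CPM, a carboxypeptidase of macrophages, at 3.26 ± 0.62 (log2 change, SE). Complement had 6 of 16 higher (6 higher and 1 lower adjusted over the list alone), among them CFP, the properdin gene (1.88 ± 0.37), and ITGAX (1.78 ± 0.30). Matrix proteases and inhibitors had 7 of 27 higher (7 adjusted over the list alone), such as TIMP2 (1.96 ± 0.39) and ADAM17 (1.83 ± 0.37); its median was -0.12, its mean per horse 0.38 and its direction in camera higher. Dendritic cell and MHC class II had 5 of 16 higher and 1 lower, with CD86 at 2.17 ± 0.56 and CD83 at 1.19 ± 0.31, and passed at an adjusted p of 0.0468 without the 24 h array of horse 2. Endothelial cell markers had 3 of 15 lower, such as ERG (-1.28 ± 0.43), and 1 higher, ENG, an endoglin that macrophages also express (3.15 ± 0.54); this list passed at an adjusted p of 0.0499 without that array. Neither list passed without it when the correlation was estimated (adjusted p = 0.417 each). Interferon-stimulated genes had 5 of 26 higher, such as STAT2 (1.37 ± 0.27), and NF-kB pathway and its early targets had 4 of 23 higher, such as NFKB1 (1.56 ± 0.31). Anti-inflammatory mediators had 4 of 19 higher, such as TNFAIP6 (1.80 ± 0.42) and TNFRSF1B (1.76 ± 0.33).

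Smaller counts stood in the rest of the lists at day 7. Hyaluronan and lubricin had 4 of 11 higher, such as CD44, the hyaluronan receptor (1.08 ± 0.25, log2 change and SE), and 1 lower, CEMIP (-0.82 ± 0.25). Apoptosis had 4 of 20 higher and 1 lower, prostaglandin and leukotriene metabolism 3 of 22 higher and 1 lower (median -0.18, mean per horse 0.16, direction in camera lower), and immediate early genes 2 of 19 higher, EGR1 (2.03 ± 0.39) and FOS (1.15 ± 0.39). Inflammatory cytokines and chemokines had 1 of 27 higher, TNF, and 2 lower, CXCL6 (-0.77 ± 0.27) and TNFSF11 (-0.62 ± 0.20). B or plasma cell markers had 1 of 13 higher, XBP1 (0.83 ± 0.28), and 2 lower, CD79B (-1.47 ± 0.42) and BLK (-0.78 ± 0.23). Synovial fibroblast markers had 1 of 15 higher, VIM (1.13 ± 0.33), and 1 lower, CLIC5. A single member was lower among red blood cell markers, CA1 (-0.73 ± 0.23), platelet markers, TUBB1 (-1.26 ± 0.31), and mast cell, basophil and eosinophil markers, GATA2 (-0.80 ± 0.26). Adjusted over the list alone, hyaluronan and lubricin had 4 higher and 2 lower, prostaglandin metabolism 2 higher, immediate early genes 1 higher, endothelial cell markers 1 higher and 4 lower, and cytokines, red blood cell and mast cell markers 0; the counts of the other lists that did not pass were as over all probe sets. Among the calls of day 7 against baseline, XBP1 lost its call in 23 of 30 settings, and FOS in 20 of 30, both also without the 24 h array of horse 2 (adjusted p = 0.0521 and 0.0518), which left 1 of 19 immediate early genes and 0 B or plasma cell markers higher. CXCL6 and TNFSF11 lost theirs in 21 of 30, ERG in 18, GATA2 in 17, CA1 in 16, SOX9 in 15, LAT and FASLG in 14, BLK and CEMIP in 13, COL6A2 in 12, and VIM and TREM1 in 11. In prostaglandin and leukotriene metabolism, ALOX5, higher, lost its call in 26 of 30 and LTC4S, lower, in 18 of 30. LTC4S also lost it without the 24 h array of horse 2 (adjusted p = 0.051), where that list had 4 higher and 0 lower. Of the calls that the rule names at day 7, 78 were higher and 36 lower; 62 and 25 of them kept their call after quantile normalization, and 53 and 15 without horse 5. None of the 32 mean changes per horse passed the exact sign-flip test, since 5 horses allow no p below 0.0625.

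**Figure D2:**
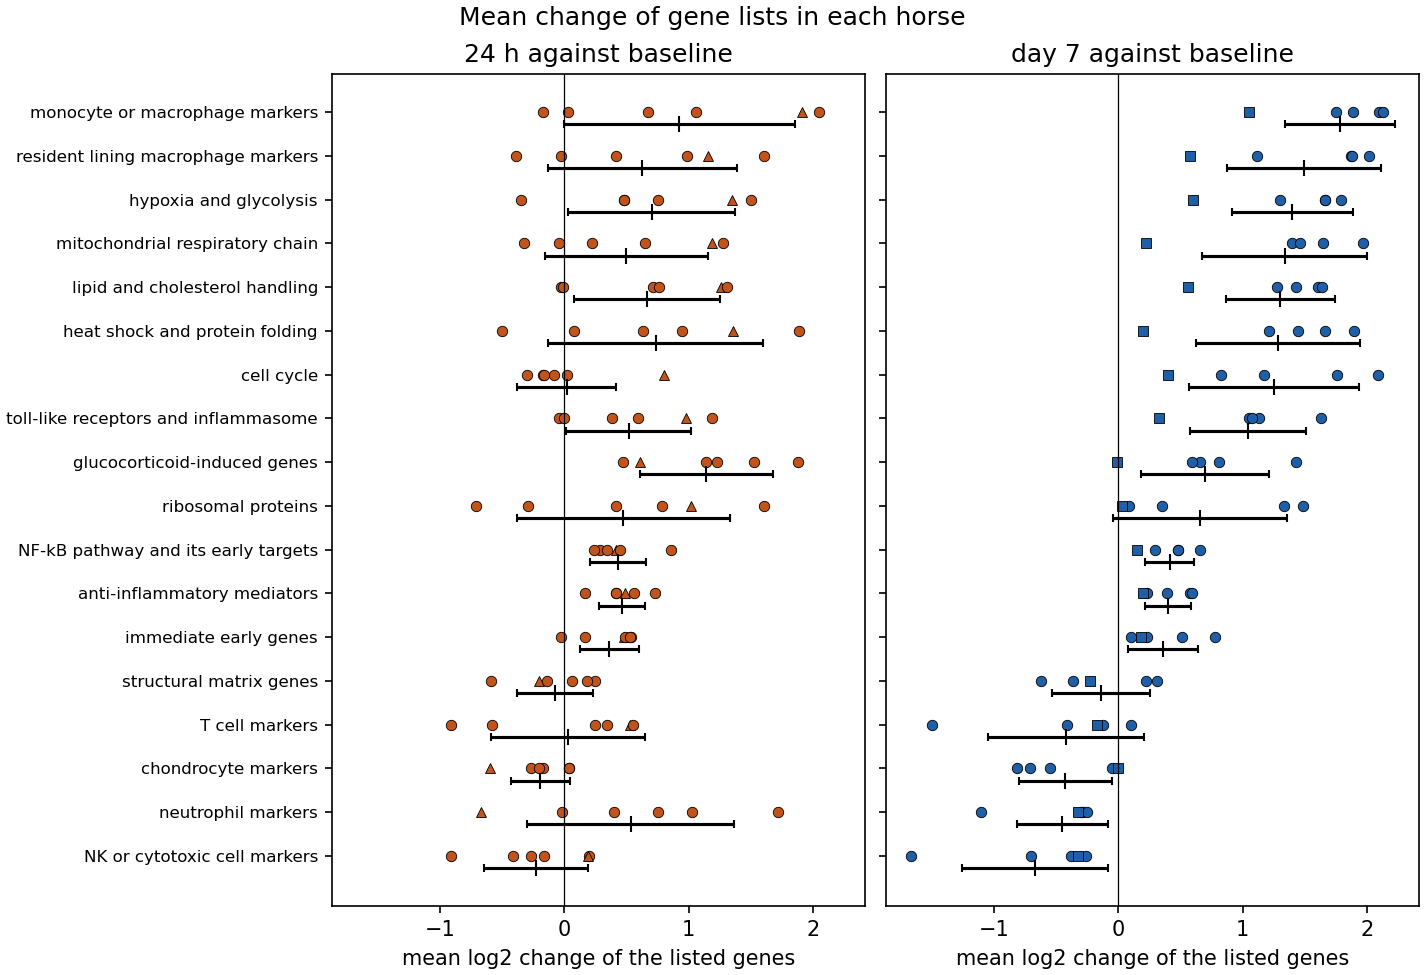
Mean log2 change of the measured genes of 18 lists in each horse, at 24 h (left) and day 7 (right) against baseline, with 1 point per horse and the mean ± SD under the points; the triangle is horse 2 at 24 h and the square the merged day 7 array. Glucocorticoid-induced genes changed by 1.15 ± 0.54 on average at 24 h, and monocyte or macrophage markers by 0.92 ± 0.93 at 24 h and 1.78 ± 0.44 at day 7.

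The third comparison asked what differed between day 7 and 24 h. No single gene passed. The largest differences included those of MMP1 and MMP8, the collagenases of stromal cells and neutrophils, which were lower on average at day 7. The log2 change of MMP1 was -3.94 ± 0.75 (SE, n = 5 horses, adjusted p = 0.166), from 8.28 ± 2.37 (SD, n = 6) to 4.54 ± 0.63 (SD, n = 5), and that of MMP8 was -3.59 ± 0.71 (adjusted p = 0.166). The merged day 7 array of horses 1 and 2 had MMP1 at 4.83 and MMP8 at 3.24, against 7.19 and 5.93 at 24 h in horse 1 and 4.20 and 3.31 in horse 2. With horses 1 and 2 taken as 1, against the mean of their 24 h arrays, both genes were lower in 5 of 5 horses. Also lower in 5 of 5 horses, counted in this way, were SLA, a signalling adaptor (-1.98 ± 0.44), NFIL3, a transcription factor (-1.69 ± 0.27), USP49 (-1.40 ± 0.29) and CSF3R, the receptor for granulocyte colony-stimulating factor (-3.08 ± 0.69). Higher at day 7 in 5 of 5 horses by the same count were LYVE1 (3.08 ± 0.55), UBE2C (2.69 ± 0.47), MKI67 (2.31 ± 0.40), ABCA9, a lipid transporter (1.81 ± 0.25), and E2F8, a cell cycle transcription factor (1.41 ± 0.25), each at an adjusted p of 0.145. TIMP1 was at 1.97 ± 0.54 (adjusted p = 0.226), C3AR1 at 2.47 ± 0.50 (adjusted p = 0.179) and CSF1R, the receptor for the main growth factor of macrophages, at 2.15 ± 0.51 (adjusted p = 0.224). FKBP5 was at -1.19 ± 0.37, PER1 at -1.49 ± 0.39, DUSP1 at -1.95 ± 0.54 and TSC22D3 at -1.27 ± 0.38, with an adjusted p between 0.224 and 0.260.

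The remaining genes chosen in advance differed less between day 7 and 24 h. The log2 change was -0.97 ± 0.33 (SE) for CXCL8, 0.73 ± 0.39 for ANXA1, 0.63 ± 0.40 for TNF, 0.44 ± 0.42 for NR3C1 and 0.41 ± 0.51 for IL1RN. It was -0.40 for COL2A1, -0.34 for MMP13, -0.25 for ACAN, -0.20 for ADAMTS4 and -0.16 each for PTGS2, COMP and MMP3. It was -0.10 for ADAMTS5, -0.03 for IL10 and -0.03 for IL6, and none passed.

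For day 7 against 24 h, limma called 0 of 30559 probe sets, with 4032 at an unadjusted p under 0.05 and a smallest adjusted p of 0.145. The count was 0 without the block, with the horse as a random effect, on the arrays of these times alone, after both other scalings, with a variance trend, without the dim probe sets, and with each array's spread as a covariate. It was 430, 253 higher and 177 lower, without the 24 h array of horse 2, and 610 without horse 2. It was 107 without the merged day 7 array, 12 with that array given to horse 1 and 0 with it given to horse 2 or with both columns kept. It was 4821 with array weights, whose fit did not converge, 1 with 1 probe set per named gene, and 1624 at an unadjusted p under 0.05 with a change of at least 2-fold. Without the 24 h array of horse 2, day 7 against 24 h gave calls for MMP1 at a log2 change of -4.65 ± 0.54 (SE, adjusted p = 0.00289), MMP8 at -4.20 ± 0.57 (0.00699), IL1R2, the decoy receptor of interleukin 1, at -3.28 ± 0.39 (0.00402) and NFIL3 at -1.82 ± 0.27 (0.0131). It also gave calls for LYVE1 at 3.51 ± 0.49 (0.00721) and MKI67 at 2.73 ± 0.26 (0.00212), and for SLA, USP49, CSF3R, UBE2C, ABCA9, E2F8, C3AR1 and CSF1R, each in the direction given above.

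Between day 7 and 24 h, 15 of the 32 lists passed camera, 9 higher and 6 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.437; the fry test passed 0, with a smallest adjusted p of 0.0905 for the cell cycle, and the exact test per horse passed 0, as 5 horses allow no p below 0.0625. Each count of called members over all probe sets was 0, so the counts that follow are adjusted over the list alone. Those counts of 0 depend on the 24 h array of horse 2. Without it 16 of 32 members of the cell cycle list were called higher, 3 of the macrophage markers, 2 each of the resident lining markers and the dendritic list, and 1 each of hypoxia and the respiratory chain. Also called higher was 1 member each of prostaglandin and leukotriene metabolism, hyaluronan and lubricin, interferon-stimulated genes and complement. Called lower were 4 neutrophil markers, 3 glucocorticoid-induced genes, 2 matrix proteases, 1 anti-inflammatory mediator and 1 immediate early gene. The median of the dendritic list was then 0.54. The cell cycle list was higher at day 7 (27 of 32 higher, median 1.20, adjusted p = 3.7e-22), as were hypoxia and glycolysis (11 of 27 higher and 1 lower, median 0.77, adjusted p = 0.0011) and the mitochondrial respiratory chain (1 of 23, median 0.77, adjusted p = 6.19e-08). Monocyte or macrophage markers (5 of 18, median 0.62, adjusted p = 0.00183), resident lining macrophage markers (3 of 14, median 0.52, adjusted p = 0.00117) and dendritic cell and MHC class II (4 of 16, median 0.36, adjusted p = 0.0258) were higher too. So were lipid and cholesterol handling (0 of 24, median 0.54, adjusted p = 0.00302), toll-like receptors and inflammasome (0 of 22, median 0.51, adjusted p = 0.0112) and heat shock and protein folding (1 of 22 lower, median 0.61, adjusted p = 0.0304). The mean change of these lists was above 0 in only 3 of 5 horses each. It was above 0 in 4 of 5 for the cell cycle, the respiratory chain and the dendritic list, and in 5 of 5 for the other higher lists. Glucocorticoid-induced genes were lower at day 7 than at 24 h (10 of 33 lower and 1 higher, median -0.66, adjusted p = 7.48e-06), with a mean change per horse of -0.57 ± 0.20 (SD, n = 5 horses), below 0 in 5 of 5 (exact p = 0.0625). Neutrophil markers were lower as well (4 of 15, median -0.50, adjusted p = 5.68e-06), and so were T cell markers (0 of 23, median -0.47, adjusted p = 0.000146) and NK or cytotoxic cell markers (0 of 17, median -0.42, adjusted p = 0.00282). The last lower lists were platelet markers (0 of 9, median -0.30, adjusted p = 0.0332) and chondrocyte markers (0 of 18, median -0.22, adjusted p = 0.0168). Among the lower lists the mean change was above 0 in 2 of 5 horses for NK or cytotoxic cell and chondrocyte markers. It was above 0 in 1 of 5 for T cell and platelet markers and in 0 of 5 for neutrophil markers. The lists that did not pass had an adjusted p from 0.0603 to 0.983; median and mean differed in sign for prostaglandin and leukotriene metabolism (-0.13 and 0.12, camera higher), apoptosis (-0.03 and 0.06, camera lower) and synovial fibroblast markers (-0.06 and 0.02, camera lower). With an estimated correlation the adjusted p of the 15 lists lay between 0.437 and 0.556, and with each array's spread as a covariate 8 lists passed, 1 of them higher.

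A single test over the time course asked which probe sets differed at any of the 3 times. The limma F test called 3968 of 30559 probe sets for any difference among the 3 times. The count was 433, 837, 151 and 370 without horses 3 to 6 in turn, 647, 953, 597 and 2087 without the day 7 arrays of horses 3 to 6, and 6592, 838, 1269, 1257 and 822 without the baseline arrays of horses 1, 2, 3, 5 and 6. It was 908 after quantile normalization and 0 with each array's spread as a covariate.

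Most probe sets called at 24 h were called in the same direction at day 7. Of the 166 probe sets called higher at 24 h, 141 were also called higher at day 7, and of the 144 called lower all 144 were lower at day 7; 0 went the opposite way. Both changes are measured against the same baseline arrays, which alone gives an overlap. In simulated unchanged groups that share them, as many top-ranked probe sets had 102 in common for the rises (at most 121) and 97.2 for the falls (at most 115). The simulated noise was drawn independently for each probe set. It leaves out the correlation between genes and the differing spread of the arrays, so the simulated range may be too narrow to judge the overlap. Independent lists would have 19.8 and 22.1. CD163, GPNMB, HMOX1, CTSB, MERTK, FKBP5, ABCA1, VCAN, TREM1 and IKBKB were called higher at both times, and GZMB, MIR187, MIR424 and LOC100050557 lower at both. Without the 24 h array of horse 2 the 24 h calls of ABCA1, VCAN and IKBKB and of these 4 lower genes were lost. MMP1, PER1 and CXCL8 were called at 24 h and not at day 7, but their difference between the times did not pass; without the 24 h array of horse 2 that of MMP1 did. Across probe sets, which are not independent replicates, the changes at 24 h and day 7 had a correlation of 0.786 and a covariance of 0.346, against 0.468 and 0.0483 in those simulated groups. When the 24 h change came from 3 horses and the day 7 change from the others, the median correlation over the 20 splits was 0.503 (0.111 to 0.676). The merged array was used only where horses 1 and 2 were both on the day 7 side, so most splits had fewer than 3 day 7 arrays.

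**Figure D3:**
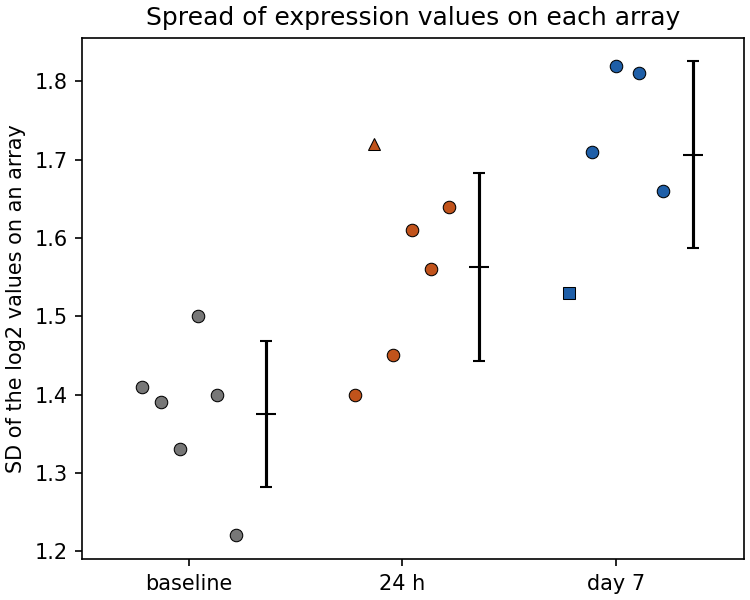
SD of the log2 values on each array at baseline, 24 h and day 7, with 1 point per array and the mean ± SD of each group; the triangle is the 24 h array of horse 2 and the square the merged day 7 array. The spread was 1.37 ± 0.0931 at baseline (n = 6), 1.56 ± 0.12 at 24 h (n = 6) and 1.70 ± 0.119 at day 7 (n = 5).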

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

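The tests of the 24 h array of horse 2, of the arrays with the widest spread, of macrophage numbers and of saline injection were chosen after the results they concern had been seen. The swaps of arrays within horses were not among the tests fixed in advance, and the others were planned.

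In the 24 h array of horse 2 the cell cycle list changed by 0.799 from baseline, against -0.302 to 0.0244 in the other horses, and MMP1 was at 4.20, against 7.19 to 10.6. On 100 genes that separate day 7 from 24 h, with 0 for the 24 h mean and 1 for the day 7 mean, this array lay at 0.871. That is outside the other 24 h arrays (-0.36 to 0.512, n = 5) and inside the day 7 arrays (0.386 to 1.32, n = 5), as a day 7 array labelled 24 h would be. Single markers were mixed. MMP1 and MMP8 (3.31) lay within the day 7 arrays other than the merged one (3.79 to 5.45 and 2.63 to 3.44). LYVE1 (5.50 against 6.87 to 8.58), MKI67 (6.69 against 6.82 to 7.63), FKBP5 (5.90 against 6.01 to 8.19) and the cell cycle mean (4.82 against 4.90 to 6.18) lay outside them and outside the other 24 h arrays. CD163 (7.71) lay within both ranges. An exchange with the merged day 7 array of horses 1 and 2 cannot be told apart from other causes: the merged array lay at 0.386, within the 24 h range, but outside the other 24 h arrays for MMP1 (4.83), MMP8 (3.24 against 5.42 to 9.75), FKBP5 (5.38 against 6.51 to 8.42), CD163 (6.60 against 6.68 to 9.78), MKI67 (6.20 against 4.16 to 4.51), LYVE1 (5.35 against 3.15 to 4.34) and the cell cycle mean (4.41 against 3.86 to 4.04), and for all of these but MMP1 and MMP8 also outside the other day 7 arrays. A faster course in this horse stays open too, because 0 later arrays are known to come from horse 2 alone. Without this array 54 probe sets were called for 24 h against baseline, 8199 for day 7 against baseline and 430 for day 7 against 24 h.

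Lower calls at day 7 lay mostly among dim probe sets, with 2634 lower and 7 higher in the dimmest of 4 equal classes by mean value. After quantile normalization, which gives every array the same spread, there were 186 lower calls in that class (7.06% of the number as deposited) and 1611 higher calls over all probe sets (44.2% of the number as deposited), which is consistent with the wider spread of values on the later arrays. The day 7 arrays of horses 4 and 5, whose spread was widest, are argued against as the whole source of the shift in that class, since its median change was -0.60 without both and -0.61 with them. The calls were mostly lost without both, with 20 higher and 44 lower left, 7 of the lower in the dimmest class, on 3 day 7 arrays. Why the spread widened after the injection was not tested, and no biological explanation was tested.

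Glucocorticoid-induced genes were higher at 24 h with a median change of 1.07. Brightness on arrays with a wider spread is argued against as the whole cause, within a limit: the median was above all 10000 random lists matched on mean value (percentile 100, range -0.05 to 0.69). The random lists were drawn gene by gene, without the correlation between genes, so their range may be too narrow. With the correlation estimated for this list, 0.149, camera gave an adjusted p of 0.107. More macrophages among the cells is a candidate explanation that cannot be told apart. From 24 h to day 7 the glucocorticoid-induced genes outside the macrophage lists changed by -0.59 ± 0.25 (SD, n = 5 horses). The macrophage markers outside the glucocorticoid list changed by 0.97 ± 0.70. The difference was -1.57 ± 0.85, below 0 in 5 of 5 horses (exact p = 0.0625, the smallest possible, two-sided sign-flip test). The rule used asked for more than 2 SD from 0, which was not reached. This SD is the spread between horses and not the error of the mean, so the rule is no test of the mean. Cells could have changed in number and in state at once, and from baseline to 24 h both sets moved up, by 0.99 ± 0.54 (exact p = 0.0312) and 0.60 ± 0.81 (n = 6 horses, exact p = 0.188). Sampling or injection without the drug stays open, with 0 arrays labelled as saline-injected, as does the drug itself, untested against it.

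Of 100 drawn splits of the baseline and 24 h arrays, the real one included, 1 gave as many called probe sets as the real 310 (highest other 32). The drawn splits move arrays without regard to the horse, while the fit is paired by horse, so they cannot exclude chance by themselves. For day 7 against baseline 1 of 100 gave as many as 8343, but the highest others came near it, with 7295 and 6530. The split with 7295 exchanged the baseline array of horse 1 and the merged day 7 array. It left the other arrays at their real time, so a real difference between the times could also give such a count. Swaps within horses, which keep the pairing, gave as many called probe sets in 1 of 32 cases at 24 h (highest other 32). That share is under 0.05, but it is the smallest that 32 cases allow and was not adjusted over the 3 comparisons. It argues only weakly against chance for the 24 h count, which was unsteady between settings. Their 16 cases at day 7, with a highest other of 0 against 8343, are too few for a share under 0.05, so chance is not excluded there. For day 7 against 24 h the real count was 0, which any split must reach (100 of 100), so the splits say nothing about chance there. A split that set the 24 h arrays of horses 2 and 6 with the day 7 arrays of horses 3 to 6 called 6038 against the real 0. That points to a structure of the samples other than the labelled times, whose cause was not tested. For any difference among the 3 times 1 of 100 splits reached 3968 (highest other 1), but these splits ignore the horses too. Chance is not excluded for the number of lists past camera: 19 of 100 splits gave at least 13 at 24 h (highest other 17), 24 of 100 at least 14 at day 7 (highest other 16), and 8 of 100 at least 15 for day 7 against 24 h (highest other 17).

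Among 150 groups of samples tested, 8 held a sample far from the others, where chance gives about 1 in 20; 1 of them is the cell cycle change of horse 2. Horse 6 had an NF-kB pathway change of 0.859 at 24 h, against 0.243 to 0.449 in the other horses. Horse 1 had a synovial fibroblast marker change of -0.851 at 24 h, against -0.177 to 0.034. At day 7 the neutrophil marker change of horse 4 was -1.10 (others -0.315 to -0.248), and the endothelial marker change of horse 5 was -0.399 (others -0.164 to -0.0713). Horse 3 differed between day 7 and 24 h with a T cell marker change of 0.463 (others -0.746 to -0.45) and a ribosomal protein change of 1.62 (others -0.439 to -0.123). The change of SLC31A1 at day 7 was 2.6 in the merged array of horses 1 and 2, against 4.52 to 5.25 in the other horses.

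The change differed between day 7 and 24 h by camera for 15 lists, given here by their median log2 change; each difference was lost with an estimated correlation. Higher at day 7 were the cell cycle (1.20), hypoxia and glycolysis (0.77), mitochondrial respiratory chain (0.77), monocyte or macrophage markers (0.62), heat shock and protein folding (0.61), lipid and cholesterol handling (0.54), resident lining macrophage markers (0.52), toll-like receptors and inflammasome (0.51) and dendritic cell and MHC class II (0.36). Lower were glucocorticoid-induced genes (-0.66), neutrophil markers (-0.50), T cell markers (-0.47), NK or cytotoxic cell markers (-0.42), platelet markers (-0.30) and chondrocyte markers (-0.22).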

How the results depend on the processing

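The settings of the merged array, of the spread covariate and of single arrays left out were chosen after the data were seen. Counts are given in the order 24 h against baseline (310), day 7 against baseline (8343), day 7 against 24 h (0) and any difference among the 3 times (3968) as far as they moved by more than 1.5 times, and unless a reason is given the cause was not tested. The horse as a random effect gave 608 at 24 h, and only the arrays of the 2 times compared 2, with fewer arrays for the spread. Quantile normalization gave 107, 2858 and 908 (any difference), and median centring 164 at 24 h. Without the dimmest of 4 brightness classes the counts were 157, 5090 and 2260 (any difference), and without probe sets below the median brightness 161, 4298 and 2296 (any difference), with fewer probe sets tested. Array weights, whose fit did not converge, gave 13636 at day 7, 4821 for day 7 against 24 h and 11419 for any difference. Unadjusted p with a 2-fold change gave 1586, 5557 and 1624, and 1 probe set per named gene, with fewer tested, gave 4941 at day 7 and 1 for day 7 against 24 h. The merged array given to horse 1 gave 494 at 24 h, 12 for day 7 against 24 h and 6332 for any difference; given to horse 2 it gave 168 at 24 h and 1950 for any difference; left out it gave 107 for day 7 against 24 h; with both columns kept there were 488 at 24 h. The spread of each array as a covariate gave 1, 0 and, for any difference, 0; the spread rises with time, so it takes up part of each change. Leaving out 1 horse or 1 array gave from 5 (horse 5) to 1257 (baseline array of horse 1) at 24 h, 1761 (horse 5) to 10934 (baseline array of horse 1) at day 7, 0 to 610 (horse 2) for day 7 against 24 h, and 151 (horse 5) to 6592 (baseline array of horse 1) for any difference. Gene lists past camera (13, 14 and 15) numbered 0, 0 and 0 with an estimated correlation, 3 at 24 h and 0 for day 7 against 24 h with fry, and 4, 4 and 8 with the spread covariate; leaving out 1 horse or array gave 11 to 16, 13 to 17 and 12 to 19. The correlation of the changes at 24 h and day 7 was 0.503 with different horses for each, against 0.786. In the 29 settings other than the spread covariate, 0 of 147 called gene results reversed; without each horse 70 to 127 kept their call, and without each array other than the merged one 94 to 145. For the 55 gene results that were not called, counted anew in each of these settings, there were 8 calls and 54 values across 0 (largest 0.43) in all. With the spread covariate 18 called changes at day 7 against baseline reversed, to -0.14 for ALOX5, 0.11 for CA1, -0.20 for CASP1, -0.09 for CD44, -0.57 for CD86, -0.18 for CPM, 0.29 for CXCL6, -0.62 for HSP90AA1, -0.21 for HSPA9, -0.21 for HSPB1, -0.17 for HSPH1, -0.15 for LTA4H, -0.05 for NFKBIB, -0.03 for TBXAS1, 0.12 for UBASH3A, -0.24 for VIM, -0.07 for XBP1 and -0.38 for XIAP. No background signal comes with the values, so what lies at the floor of the array is not known.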

Other observations

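Lists of lysosomal, iron and redox genes passed camera as higher at day 7 but not with an estimated correlation, on arrays whose spread of values was also wider (SD 1.70 against 1.37 at baseline). Monocyte or macrophage markers were higher on the same arrays (11 of 18 called, median 1.81), and the lists were not tested apart from these markers. These 3 lists were written after the genes with the largest rises had been seen, and they leave those genes out; their tests were set before their other members were looked at. Of 29 lysosome genes 24 rose and 0 fell, with a median log2 change of 1.68 (camera adjusted p over the 3 lists 4.29e-13, adjusted p = 0.136 with an estimated correlation), and the mean change per horse was 1.88 ± 0.73 (SD, n = 5 horses), above 0 in 5 of 5. CD63, a membrane protein of late endosomes, rose by 3.25 ± 0.69 (SE), the cathepsin CTSZ by 3.05 ± 0.53, the protective protein CTSA by 2.73 ± 0.44, and the membrane protein LAMP1 by 2.46 ± 0.42. Of 16 haem and iron genes 10 rose and 1 fell (1 of the 16 is in another list; median 0.92, adjusted p = 0.000775, adjusted p = 0.136 with an estimated correlation). LRP1, a receptor that takes up haem bound to hemopexin, rose by 2.51 ± 0.46, ACO1, an iron-responsive regulator, by 1.79 ± 0.32, and TFRC, the transferrin receptor, by 1.43 ± 0.43; CP, the ceruloplasmin gene, fell by 0.54 (SE 0.17). Of 13 NRF2 targets 7 rose and 0 fell (median 0.83, adjusted p = 0.00693, adjusted p = 0.136 with an estimated correlation), among them TKT and TALDO1 of the pentose phosphate pathway (2.36 ± 0.38 and 1.56 ± 0.28) and TXN, the thioredoxin gene (2.10 ± 0.64). Other members of this list did not pass, such as NQO1 (0.09), SLC7A11 (-0.05) and GSTA4 (-0.62).

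At 24 h the same lists had fewer calls. Of the lysosome genes 3 of 29 rose (median 0.90, adjusted p = 2.91e-10, adjusted p = 0.193 with an estimated correlation), of the haem and iron genes 1 of 16 (median 0.45, adjusted p = 0.00217, adjusted p = 0.193 with an estimated correlation), and of the NRF2 targets 1 of 13, as a list not past the threshold (median 0.43, adjusted p = 0.0533). Between day 7 and 24 h none of their members was called by limma, and the median differences were 0.80, 0.30 and 0.27. The 3 lists passed camera as higher at day 7 than at 24 h (adjusted p = 1.63e-09, 0.0121 and 0.0111), but not with an estimated correlation (adjusted p = 0.209, 0.22 and 0.209). Their mean change between these times was above 0 in 3, 3 and 5 of 5 horses.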
